A study of Mus musculus with 10 samples.

How the data were processed

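Barcodes were sequenced from genomic DNA of sorted viable mouse leukaemia cells. Per the labels' protocols, c-Kit-positive haematopoietic progenitors in culture with IL-3, IL-6 and SCF had been transduced with SPLINTR barcode libraries, cells were lysed, the lysate was split into technical replicates, and barcodes were amplified in 2 rounds of PCR with a dual index per well. The submitters' processing notes list Bowtie 1.2.2 and R 3.6. The reference list of barcodes, filters on barcodes and the way technical replicates were combined are not given in the sources used here. The deposited values are CPM, barcode reads scaled to a common total, and each of the 10 columns summed to 1000000. Each column was matched to its sample by the donor, strain and tissue in its name, and 0 columns belonged to other samples.

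Samples were grouped by strain, tissue and timepoint from their titles into baseline, NSG bone marrow, NSG spleen, PTPRCA bone marrow and PTPRCA spleen, with donor mouse 1 and donor mouse 2 as replicates. Same-numbered samples came from the same donor mouse, per the labels, so that the numbers pair samples. Deviations from the group means correlated between same-numbered samples at 0.466 to 0.944 over the 10 pairs of groups (3443 clones).

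Depth was read from the low CPM values. In 8 columns these were sums of whole multiples of 2 steps, in donor 1 NSG spleen of 3 and in donor 2 NSG bone marrow of 4, so that each column equals the mean of that many CPM-scaled libraries. The step sizes gave whole read totals for all 23 libraries (largest distance from a whole number 0.00972 reads, tolerance 0.05). For the 8 columns with 2 libraries, values up to 1000 CPM were split into the reads of each library, which had 1 solution for 99.0% to 99.9% of values. On simulated data, 2680 values were split, all correctly, and 68 were left unsplit. Since no single step gives whole reads for nearly all values of a column, no count model was run on the whole table.

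Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1, were used. For each sample the effective number of clones (exponential of Shannon entropy), the number of clones with at least 100 CPM and the share of reads per barcode library were computed. Differences of log2 values were tested with two-sided exact permutation tests, exchanging strains within donors (smallest p 0.5), exchanging which of the 5 samples of each donor is the baseline (smallest p 0.04) and flipping the sign of the 4 spleen minus marrow pairs (smallest p 0.125). Clones were tested with limma (lmFit and eBayes with a trend) on log2(CPM + 10), with 1 mean per group over all 10 samples, for the 3443 clones with at least 100 CPM in 1 or more samples, and called at a Benjamini-Hochberg adjusted p below 0.05. A fold on this scale understates the change of rare clones. The limma step was checked on simulated data with 200 changed clones among 3443 for NSG against PTPRCA. It recovered 99.5% and 100% of clones changed in both donors by log2 folds of 2 and 4, with 3 and 5 false calls, and 0% of clones present in 1 donor, when noise had an SD of 0.5 log2 and donors did not differ. With donors apart clone by clone as in the data, it recovered 0% at both folds. The fit with a donor block recovered 100%, with 9 and 13 false calls, where noise was independent between all samples, marrow and spleen included. In the data, clones called between strains by the block fit had SEs of 0.853 to 1.01 log2, above even the simulated SD of 0.5. Recovery was thus measured on quieter data than these.

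Bray-Curtis similarity was computed on clone shares. The baseline list held the 10 clones with the highest share in the same donor's baseline. A clone was called dominant at 1% of reads or more. Clones named in the text are the 5 largest of each donor at baseline, and in each strain at disease, clones dominant in both donors, clones called by limma (up to 5 per direction) and, where none was called, up to 3 per direction with the largest mean difference of 1 sign in both donors. Clones called with donor as a block, and the clones found in both baselines were named after their values were seen.

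The comparisons of diversity, similarity, baseline list, dominance and limma calls, their alternatives and the naming rule were fixed before the data were examined. The alternatives were donor as a block, pseudocounts of 1 and 100 CPM, no filter or a filter of 1000 CPM, inverse Simpson numbers, clones of at least 100 CPM only, other similarity measures, other list sizes and thresholds, and each donor left out. Added after seeing the data were the comparison within each donor of clones over 4-fold apart by strain in both tissues or by tissue in both strains, with its alternatives, a limma fit within each donor, the donor block together with each other limma alternative or with the mean of marrow and spleen, the tests of colour shares, the clones found in both baselines, and removal of the largest clone, of the largest BFP clone of each sample, of all GFP barcodes, of donor 1 clones from the donor 2 baseline, or of the 2 samples whose libraries differ.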

Results

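The study followed barcoded mouse leukaemia clones through retransplantation. Haematopoietic progenitor cells expressing the c-Kit receptor had been marked with SPLINTR libraries, lentiviral pools in which each integrated DNA barcode labels a cell and its descendants, and the labels describe the cells as an MLL-AF9 leukaemia, driven by a fusion of the Kmt2a (MLL) and Mllt3 (AF9) genes. Cells of 2 donor mice were transplanted into Ptprca mice, which carry a variant of the CD45 gene and have a working immune system, or into NSG mice, which lack T, B and natural killer cells. Each donor gave 5 samples, namely the baseline cells and the bone marrow and spleen of each recipient strain at disease, so that 10 samples fell into 5 groups with 2 donors each.

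Barcode abundance was given in CPM (barcode reads scaled to a total of 1000000 per sample), 1 value per barcode and sample, over 19704 listed barcodes of the BFP, GFP and mCHERRY libraries. A barcode was read as 1 clone, and 11601 barcodes had reads in at least 1 sample. The low values showed each sample to be the mean of 2 to 4 sequenced libraries of 1591539 to 4475416 reads, with 5171235 to 10394809 reads per sample. A value of 3 reads, the upper 95% limit for a count of 0, corresponded to between 0.289 and 0.580 CPM. Counting error on the share of a colour or of the largest clone was at most 0.0427 percentage points on either side (95% Wilson interval). These limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The labels did not say how many recipients a sample came from, so that a difference between strains could not be separated from one between individual recipients.

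The first comparison set the disease samples against the donor's baseline and asked how the clonal composition changed between transplantation and disease. Disease samples held fewer clones than the baselines. The effective number of clones, the exponential of the Shannon entropy of clone shares, was 149 ± 29.5 (SD, n = 2) at baseline and between 38.4 ± 10.96 (PTPRCA spleen, SD, n = 2) and 67.6 ± 15.1 (NSG bone marrow, SD, n = 2) at disease. Clones with at least 100 CPM numbered 1132 and 1257 in the baselines of donors 1 and 2 and 356 to 571 in the disease samples. The mean decrease of the effective number was 2.96-fold, a log2 difference of -1.56 (two-sided exact permutation test of which sample of each donor was the baseline, p = 0.04, the smallest this test allows). The test exchanges marrow and spleen of a donor and strain as separate samples, so that its p overstates the evidence. Counted as 1 sample, they would allow no p below 0.05. All 8 disease samples lay below their donor's baseline. Inverse Simpson numbers, which weight the largest clones most, differed by a log2 value of -0.052 (exact permutation p = 0.68).

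**Figure D1:**
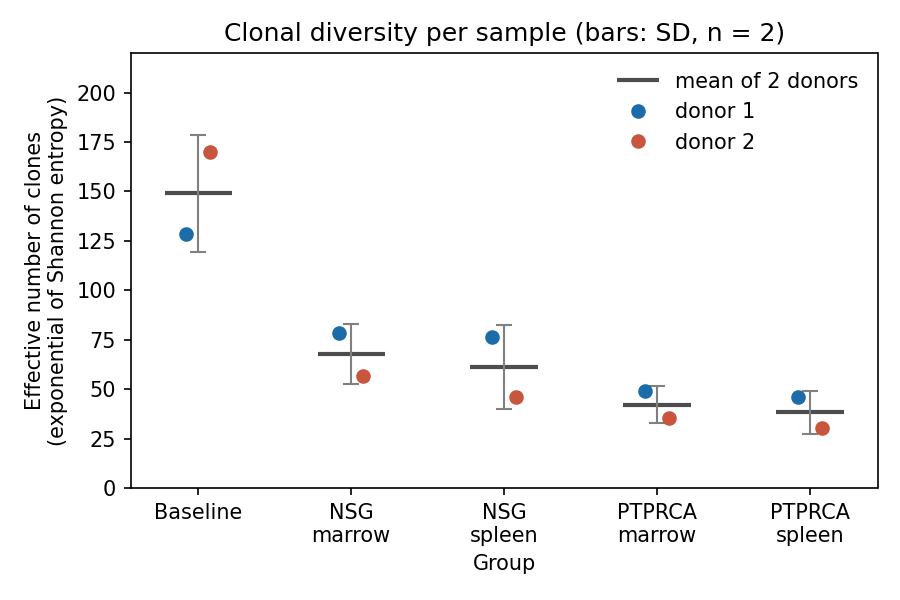
Effective number of clones (vertical axis, exponential of the Shannon entropy of clone shares, no unit) for each group (horizontal axis), with 1 point per donor, a horizontal bar for the mean and error bars for the SD (n = 2). Baselines sit at 128 and 170, NSG samples between 46.3 and 78.4, and PTPRCA samples between 30.6 and 48.9.

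The clones that filled the disease samples were mostly below 0.1% at baseline, as were most baseline clones. In donor 1, 32 clones reached 1% of reads in a disease sample, 25 of them mCHERRY, 4 BFP and 3 GFP, and 27 of the 32 had been below 0.1% at baseline. In donor 2, 19 clones did so, 15 of them mCHERRY, 1 BFP and 3 GFP, and 13 had been below 0.1%. Of baseline clones at 100 CPM or more, at least 1016 of 1132 (donor 1) and 1130 of 1257 (donor 2) were also below 0.1%. A low baseline share was thus not particular to the dominant clones. In donor 2, mCHERRY_2_Barcode_311488 stood at 0.155% at baseline and at 4.40% to 9.09% in the disease samples, and mCHERRY_2_Barcode_187286 at 0.119% and at 2.49% to 10.2%. In donor 1, mCHERRY_2_Barcode_8041 stood at 0.0371% at baseline and averaged 3.43% over the 4 disease samples, 92.4-fold higher.

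The 4 clones outside the GFP library among the 5 largest of each baseline stood lower at disease. Among the 5 largest baseline clones of donor 1, mCHERRY_2_Barcode_552621 went from 0.755% to a mean of 0.00902%. Among those of donor 2, mCHERRY_2_Barcode_1134094 went from 0.619% to a mean of 0.000521%, mCHERRY_2_Barcode_927520 from 0.460% to 0.0106% and BFP_Barcode_2119 from 0.409% to 0.0441%. Of all clones with at least 100 CPM at baseline, 41.2% to 56.1% were below 3 reads in a given disease sample, and 7.64% to 11.9% had at least doubled. Spearman's rho between baseline and disease abundance over these clones ranged from -0.0141 to 0.211, across clones, which are not independent replicates.

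One clone, GFP_Barcode_52804, held a large share in all 10 samples. It made up 29.8% of donor 1 and 36.7% of donor 2 reads at baseline, and 21.1% to 42.2% of reads at disease. The 10 largest baseline clones held 39.2% ± 3.75 (SD, n = 8) of reads at disease against a mean of 48.1% at baseline. In an alternative chosen after the data were seen, GFP_Barcode_52804 was removed and the list drawn again from the other clones. These 10 clones held a mean of 7.73% ± 10.3 (SD, n = 8) of the remaining reads at disease, against 22.2% at baseline. Their share was 5.85% to 11.6% in 3 disease samples of donor 1 and 31.5% in its PTPRCA spleen, from 33.7% at baseline. In donor 2 it was 0.0751% to 2.98%, from 10.7%. A list of 10 drawn again without any GFP barcode held 0.149% ± 0.0915 (SD, n = 8) of the remaining reads at disease and 7.21% at baseline.

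The share of each barcode library, compared after the data were seen, shifted between baseline and disease. The mCHERRY share was 24.3% and 29.3% in the baselines of donors 1 and 2, and 42.6% to 57.8% at disease, a mean rise of 1.86-fold. The BFP share was 22.6% and 29.1% at baseline and 5.30% to 21.97% at disease, a mean decrease of 2.86-fold, and was below the baseline in all 8 disease samples. The decrease was uneven, at log2 -0.92 in donor 1 (exact permutation p = 0.6 in this donor alone, where 0.2 is the smallest possible) and -2.11 in donor 2, and in NSG of donor 1 the share was 19.9% and 21.97% against 22.6% at baseline. Baseline BFP clones of at least 100 CPM fell below 3 reads in 57.2% to 76.2% of cases per sample, and mCHERRY clones in 16.3% to 47.5%. Among clones of 100 to 300 CPM at baseline these ranges were 59.0% to 76.2% and 19.4% to 47.2%, although BFP clones were the rarer ones within that window (median 143.0 against 170.4 CPM in donor 1 and 157.9 against 169.0 CPM in donor 2). Each share difference had an exact permutation p of 0.04, the smallest this test allows, which also counts marrow and spleen as separate samples. The Benjamini-Hochberg adjusted p was 0.144 over 18 permutation tests of colour shares and clone counts, so that neither passed the adjusted threshold.

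**Figure D2:**
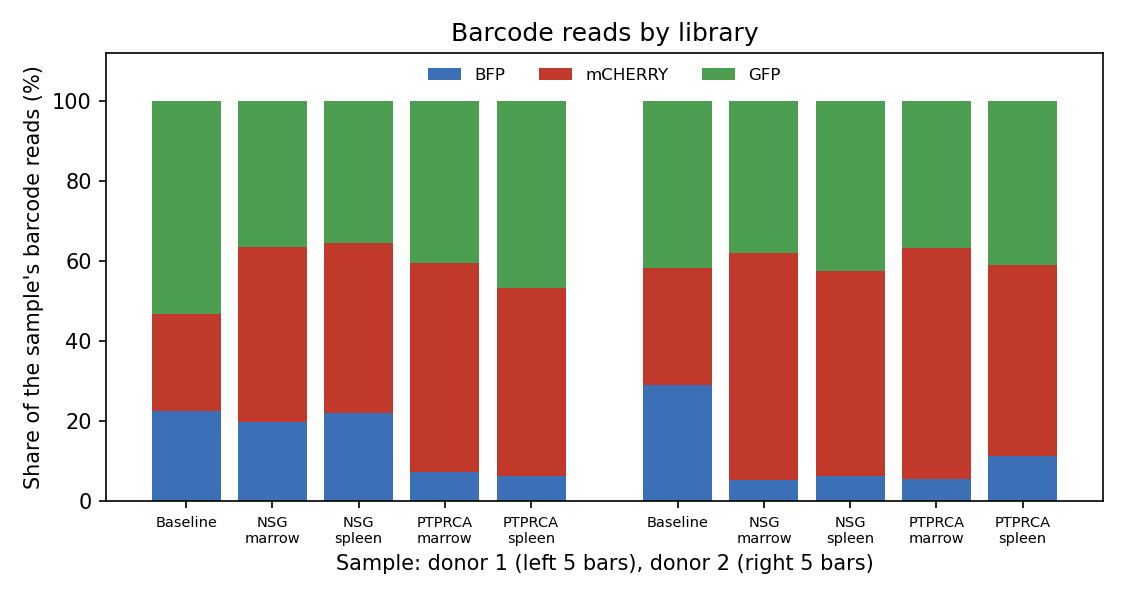
Share of the reads of each sample (vertical axis, per cent) that belonged to BFP, mCHERRY and GFP barcodes, in stacked bars for donor 1 (left) and donor 2 (right). The mCHERRY part was 24.3% and 29.3% in the baselines and at least 42.6% in each disease sample.

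Clone by clone, limma on log2(CPM + 10) over 3443 clones called 0 clones between disease and baseline, with 468 at an unadjusted p below 0.05. With donor as a block it called 5, all lower at disease, namely GFP_Barcode_113643 (log2 -6.74 ± 1.01 SE, adjusted p = 1.02e-07 by limma), GFP_Barcode_38818 (-5.57), GFP_Barcode_69276 (-5.27), BFP_Barcode_139027 (-4.91) and GFP_Barcode_7083 (-4.79). BFP_Barcode_139027 was at 241 and 349 CPM in the baselines and was listed at 0 in all 8 disease samples. The block fit counts marrow and spleen of a donor and strain as separate samples, and with their mean in place of both it called GFP_Barcode_113643 and GFP_Barcode_69276 only. With the block and no filter on abundance limma called 0 of 11601 clones, with 2342 at an unadjusted p below 0.05. Without the block, the 3 clones highest at disease among those with 1 sign in both donors were GFP_Barcode_40977, mCHERRY_2_Barcode_187286 and mCHERRY_2_Barcode_311488, with mean log2 differences of 2.99, 2.67 and 2.61. The difference of the mCHERRY pair lay almost wholly in donor 2, at 5.34 and 5.21 against 0.0075 and 0.014 in donor 1.

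The second comparison set NSG against PTPRCA recipients and asked whether the immune status of the host shaped the clones that grew. Within each donor, many clones differed between the strains, and in the same direction in marrow and spleen. In donor 1, 335 of 1722 clones were over 4-fold apart in both tissues, 221 of them higher in NSG and 114 higher in PTPRCA, and 4 had opposite signs. In donor 2, 268 of 1736 clones were, 175 higher in NSG and 93 higher in PTPRCA, and 5 had opposite signs. The strain differences in marrow and in spleen correlated at r = 0.71 in donor 1 and 0.69 in donor 2, across clones, which are not independent replicates. This comparison was chosen after the data were seen, and no test over animals was possible within 1 donor. A limma fit within each donor called 0 clones, with 333 of 1722 and 284 of 1736 clones at an unadjusted p below 0.05. It fits strain and tissue to 4 samples, which leaves 1 residual degree of freedom per clone. Its 0 calls therefore say little about whether clones differed.

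Single clones illustrate the size of these differences. In donor 1, mCHERRY_2_Barcode_663729 held 1.17% and 5.11% of NSG marrow and spleen and 0.0596% and 0.0876% of PTPRCA marrow and spleen, a ratio of mean shares of 42.6. In the same donor BFP_Barcode_112923 held 1.68% and 0.635% in NSG and 0.00366% and 0.000238% in PTPRCA. In donor 2, BFP_Barcode_97773 held 1.32% and 7.54% of PTPRCA marrow and spleen and 0.0582% and 0.0353% of NSG marrow and spleen, 94.7-fold higher in PTPRCA by mean share. Also in donor 2, mCHERRY_2_Barcode_529484 averaged 1.79% in NSG and 0.344% in PTPRCA. Other leading clones differed little, such as mCHERRY_2_Barcode_96127 of donor 2 with 2.49% in NSG and 3.20% in PTPRCA.

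Barcodes found in both baselines were compared across the 2 donors, a comparison chosen after the data were seen. Whether such a barcode marks 1 clone held by both donors or separate cells that took up the same barcode could not be told from the labels or the values. Only 10 barcodes had at least 100 CPM in both baselines, 7 of them GFP, 3 BFP and 0 mCHERRY, against 123 for independent lists. This deficit lay in the BFP and mCHERRY libraries. Of 485 listed GFP barcodes, 21 and 19 reached 100 CPM in the baselines of donors 1 and 2. The 7 shared are more than independent lists of these sizes would hold. Of the 7 GFP clones, 5 were lower in NSG than in PTPRCA in both tissues of both donors. None of the 3 BFP barcodes was, but each was listed at 0 in both PTPRCA samples of at least 1 donor. None could therefore lie lower in NSG in both donors, so that these 3 are no contrast to the GFP clones. Their mean log2 NSG over PTPRCA in donors 1 and 2 was 1.83 and 0 (BFP_Barcode_27084), 0.081 and -0.88 (BFP_Barcode_213231), and 0 and 0 (BFP_Barcode_139027). GFP_Barcode_52357 averaged 2.64% in NSG and 10.9% in PTPRCA of donor 1, and 0.0353% and 1.56% in donor 2, 4.13-fold and 44.3-fold lower in NSG. GFP_Barcode_69276 stood in donor 1 at 1111 CPM in NSG against 1604 CPM in PTPRCA marrow, where the NSG libraries differed. In spleen of donor 1 it stood at 72.7 CPM against 7461 CPM, where the PTPRCA libraries differed. In donor 2 it stood at 8.49 CPM against 1043 CPM in marrow and at 0 against 428 CPM in spleen, and GFP_Barcode_7083, GFP_Barcode_38818 and GFP_Barcode_113643 had the same direction. GFP_Barcode_98919 differed in sign between tissues, and GFP_Barcode_52804 differed by log2 0.26 and 0.092. At least 1% of disease reads in both donors was reached by 2 clones, GFP_Barcode_52804 and GFP_Barcode_52357 (Fisher's exact test among the 10 clones, two-sided p = 0.0667). At 0.1% of reads 3 clones did so, GFP_Barcode_69276 being the third (Fisher's exact test, p = 0.0333), and at 5% of reads GFP_Barcode_52804 alone (p = 0.3 by the same exact test).

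**Figure D3:**
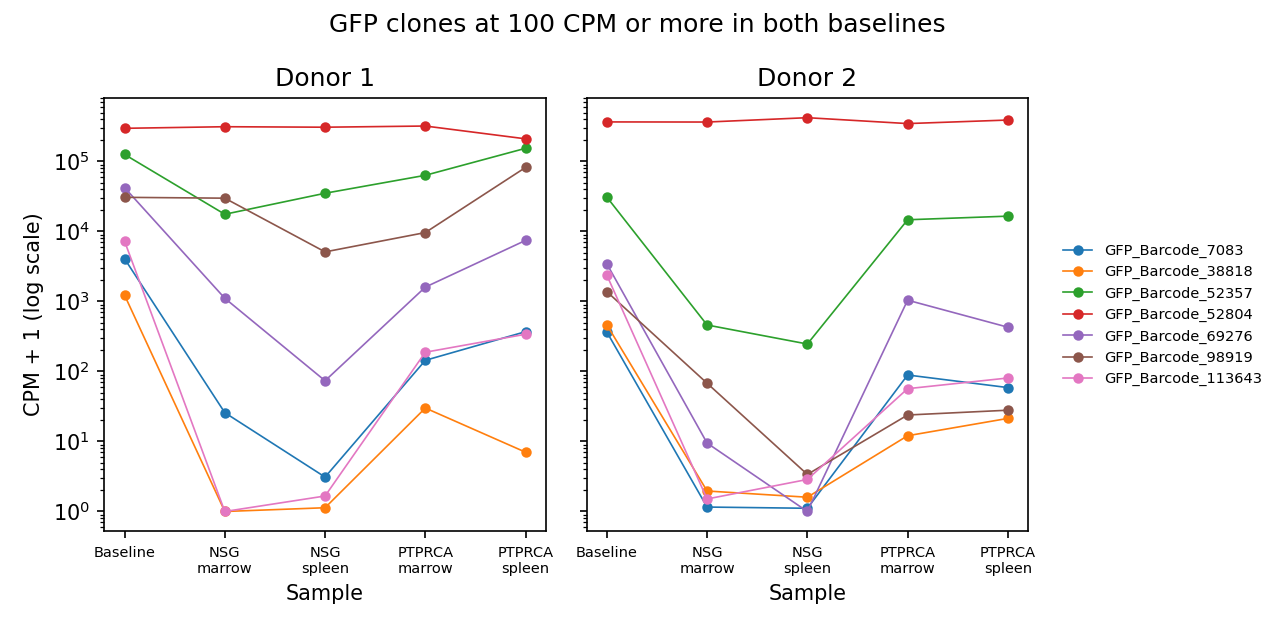
Abundance (vertical axis, CPM + 1, log scale) of the 7 GFP clones with at least 100 CPM in both baselines, in the 5 samples (horizontal axis) of donor 1 (left) and donor 2 (right), with 1 line per clone that joins separate samples and does not show a course in time. In both donors 5 clones lie lower in both NSG samples than in both PTPRCA samples, while GFP_Barcode_52804 lies between 210589 and 422235 CPM throughout.

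Over all clones, limma called 0 between the strains, with 1 clone at an unadjusted p below 0.05. In data simulated with donors as far apart as these and other noise of 0.5 log2 (SD), this fit recovered 0% of clones changed by a log2 fold of 2. With donor as a block limma called 10 clones, counting marrow and spleen of a donor and strain as separate samples. With the mean of both tissues in their place, so that 2 donors bear on the strain, it called 0, with 18 clones at an unadjusted p below 0.05, so that the adjusted p of these 10 clones overstate the evidence. With the block and no filter on abundance it also called 0 between strains, with 153 clones at an unadjusted p below 0.05. Of the 10 clones, those higher in NSG were GFP_Barcode_40977 (log2 5.97 ± 0.95 SE, adjusted p = 1.26e-06 by limma), mCHERRY_2_Barcode_63551 (4.53), BFP_Barcode_112923 (4.37), mCHERRY_2_Barcode_348373 (4.17) and BFP_Barcode_271065 (3.80). Lower in NSG were GFP_Barcode_69276 (-4.58 ± 0.85 SE, adjusted p = 1.43e-04 by limma), GFP_Barcode_3138 (-3.87), mCHERRY_2_Barcode_364642 (-3.82), GFP_Barcode_52357 (-3.74) and GFP_Barcode_113643 (-3.73). The 5 GFP clones reached 100 CPM in both donors, and the other 5 in 1 donor only. GFP_Barcode_40977 was listed at 0 in both baselines, all 4 PTPRCA samples and donor 1 NSG bone marrow. It held 1.16% and 0.269% of NSG marrow and spleen in donor 2 and 0.0488% of NSG spleen in donor 1. It was 1 of 28 barcodes at 0 in both baselines that reached 10 CPM in NSG samples of both donors, against 8.28 for independent lists.

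Clonal diversity was higher in NSG than in PTPRCA in both donors and both tissues. In donor 1 the effective number was 78.4 and 76.2 in NSG marrow and spleen and 48.9 and 46.1 in PTPRCA marrow and spleen. In donor 2 it was 56.9 and 46.3 against 35.7 and 30.6. The mean difference was 1.59-fold, a log2 value of 0.67, with an exact permutation p of 0.5, the smallest that exchanging strains within 2 donors allows, so that the test could not separate it from chance. The ratio was 2.46-fold without GFP_Barcode_52804, and by inverse Simpson numbers the sign turned (log2 -0.074).

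The colour of the clones that differed by strain was compared within each donor, and the difference between donors was not tested. In donor 1, the BFP share was 19.9% and 21.97% in NSG against 7.26% and 6.39% in PTPRCA, and of the BFP clones over 4-fold apart in both tissues 154 were higher in NSG and 14 in PTPRCA, against 65 and 93 mCHERRY clones (Fisher's exact test over clones, p = 1.64e-23). In donor 2, the BFP share was 5.30% and 6.18% in NSG and 5.59% and 11.4% in PTPRCA, of which BFP_Barcode_97773 made up 1.32% in PTPRCA marrow and 7.54% in PTPRCA spleen. With the largest BFP clone of each sample left out in both donors, a setting chosen after the data were seen, the mean log2 NSG over PTPRCA was 1.78 in donor 1 and 0.44 in donor 2, against 1.62 and -0.48 with all clones. The clones of donor 2 split 59 to 35 for BFP and 115 to 51 for mCHERRY (Fisher's exact test over clones, p = 0.337). GFP clones were higher in PTPRCA in 7 of 9 cases in donor 1 and 7 of 8 in donor 2. These tests treat clones as independent, although clones of 1 sample share recipients.

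The third comparison set spleen against bone marrow and asked whether clones settled by tissue. Few clones differed between tissues in a repeated way. In donor 1, 16 of 1722 clones were over 4-fold apart in both strains with the same sign and 13 with opposite signs. In donor 2, 9 of 1736 clones were, and 10 had opposite signs. The tissue differences in NSG and PTPRCA correlated across clones at r = 0.0080 in donor 1 and -0.020 in donor 2. Limma called 0 clones, also with donor as a block, with 0 clones at an unadjusted p below 0.05 without the block. The clones with the largest mean difference of 1 sign in both donors were BFP_Barcode_565785, at log2 -0.92 and -1.89 in donors 1 and 2, and BFP_Barcode_100420, at 0.11 and 1.81. The effective number was lower in spleen in all 4 pairs by a mean log2 value of -0.16 (exact sign-flip permutation p = 0.125, the smallest 4 pairs allow). Without GFP_Barcode_52804 it was higher in spleen in donor 2, at 235 against 208 in NSG and 91.7 against 89.2 in PTPRCA (mean log2 -0.19, exact permutation p = 0.75). The mean log2 difference was -0.024 without GFP barcodes (exact permutation p = 0.875) and -0.026 by inverse Simpson numbers (exact permutation p = 1).

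**Figure D4:**
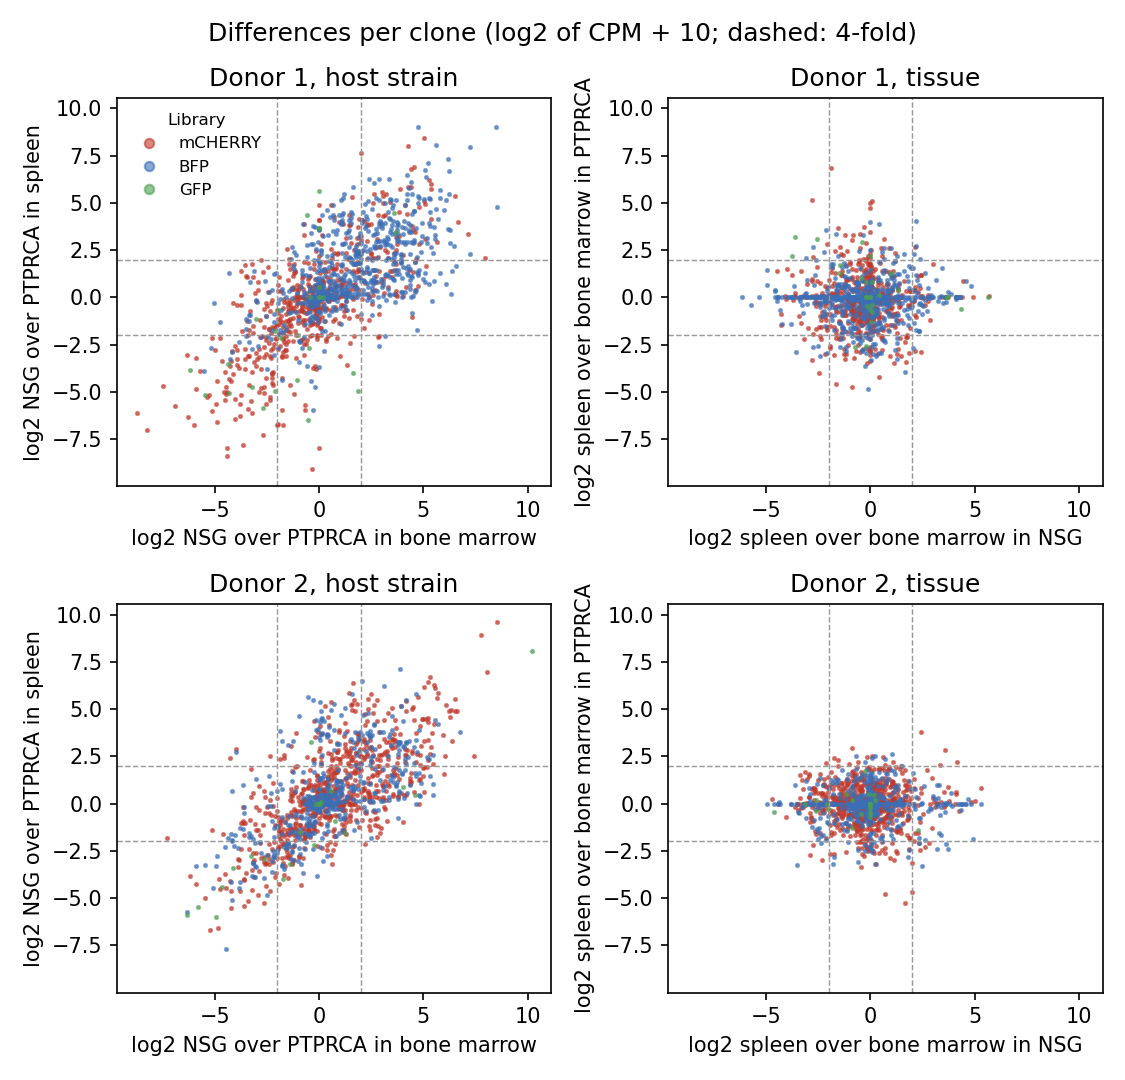
Log2 difference of CPM + 10 per clone, as NSG over PTPRCA in bone marrow (horizontal axis) against spleen (vertical axis) on the left, and as spleen over bone marrow in NSG (horizontal axis) against PTPRCA (vertical axis) on the right, for donor 1 (top) and donor 2 (bottom), with 1 point per clone coloured by library and dashed lines at 4-fold. Strain differences follow the diagonal (r = 0.71 and 0.69) and tissue differences do not (r = 0.0080 and -0.020).

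Overlap of clone shares was compared between pairs of samples. Bray-Curtis similarity, the share of reads that 2 samples have in common clone by clone, was 0.725 ± 0.078 (SD, 4 pairs) between marrow and spleen of the same donor and strain. It was 0.606 ± 0.087 (SD, 4 pairs) between NSG and PTPRCA of the same donor and tissue, 0.448 ± 0.029 (SD, 8 pairs) between disease and baseline, and 0.298 ± 0.048 (SD, 4 pairs) between donors at disease. Pairs shared samples, so that these values were not tested. By Morisita-Horn similarity, which weights the largest clones most, disease and baseline (0.935) were closer than NSG and PTPRCA (0.925), which turns that order. Without GFP_Barcode_52804 the Bray-Curtis values were 0.634, 0.443, 0.192 and 0.0144, in the order of pairs given above. The last was 0.0016 and 0.0022 in NSG and 0.0248 and 0.0289 in PTPRCA, and the baselines of the donors had 0.0667.

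Libraries of the same sample did not agree equally well, which bears on donor 1 in particular. The median absolute log2 ratio between the 2 libraries of a sample, over clones of 100 to 1000 CPM, was 0.046 to 0.28 in 6 of the 8 samples with 2 libraries. It was 0.66 in donor 1 NSG bone marrow and 1.27 in donor 1 PTPRCA spleen, where 33.2% of clones were over 4-fold apart. Counting error alone gave 0.036 to 0.052. The 2 other samples of donor 1 at disease, NSG spleen and PTPRCA bone marrow, had 508 of 1722 clones over 4-fold apart, against 548 between the strains in marrow and 527 in spleen. That NSG spleen, of 3 libraries, was not split, so that the agreement of its libraries is unknown. The second library of the donor 2 baseline held reads of 169 clones of donor 1, 0.148% of the sample, and without donor 1 clones the disease difference in diversity was a log2 value of -1.55.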

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

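All tests of explanations in this part were chosen after the results were seen. The BFP share moved in opposite directions between strains in the donors, by a log2 NSG over PTPRCA of 1.62 in donor 1 and -0.48 in donor 2, with both tissues of a donor on the same side. With the largest BFP clone of each sample left out in both donors, these values were 1.78 and 0.44, so that the sign in donor 2 turned. The GFP share did likewise, by -0.28 in donor 1 and 0.053 in donor 2. Neither difference between donors was tested.

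Clones of donor 1 appeared at low level in the baseline of donor 2. Of 218 clones with at least 1000 CPM in a disease sample of donor 1 and under 1 CPM in every disease sample of donor 2, 169 had reads in the donor 2 baseline at a median of 5.14 CPM, and 99.4% of these had reads in the second of its 2 libraries only, against 0.726% of donor 2's own clones. Clones that both donors carried would divide between the libraries as the other clones do, yet the first library held 1.78% of their reads against 53.7% for donor 2's own clones, which argues against a shared origin. Material of donor 1 in the second library may therefore account for them, and they made up 0.148% of the sample's reads. Their levels followed donor 1 NSG bone marrow best (Spearman's rho 0.544 across clones).

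Strain differences repeated in both tissues of a donor, while tissue differences did not repeat in both strains. Uneven PCR libraries as the whole cause would scatter both alike. In donor 2, whose split libraries agreed well, the ratio of clones apart by tissue to clones apart by strain was 0.0336. Its NSG bone marrow, of 4 libraries, was not split, and 242 of its clones were over 4-fold apart by tissue in NSG. Among its split samples, 468 clones were over 4-fold apart by strain in spleen and 88 by tissue in PTPRCA. These values argue against uneven libraries as the whole cause. Chance outgrowth in each set of recipients, with marrow and spleen of the same recipients sharing it, cannot be told apart from an effect of the host strain, because only 3 clones outside the GFP library were found in both baselines. Host strain stays open. Over the 2 donors, limma with the block on the mean of marrow and spleen called 0 clones, and individual recipients could not be tested.

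The 5 GFP clones lower in NSG in both donors, with GFP_Barcode_98919 by mean log2 value as a 6th, were the pattern shared by the donors. By mean share, GFP_Barcode_98919 was higher in NSG in donor 2, at 34.7 against 24.9 CPM. None of 19 clones outside the GFP library that were dominant in donor 1 PTPRCA exceeded 0.00255% of its donor 1 level in donor 2 PTPRCA. The 6 GFP clones stood at 0.0543% to 89.7% of theirs, with a median of 21.0%, and 5 of them at over 1%. For those 5, these values argue against carry-over of donor 1 PTPRCA material at large into the PTPRCA samples of donor 2. Carry-over of GFP barcodes alone was not tested. All 7 GFP clones had 1 sign in both donors (two-sided exact binomial p = 0.0156). With a pseudocount of 100 CPM 6 of 7 did (exact binomial p = 0.125), where GFP_Barcode_98919 changed sign in donor 2. The binomial test takes clones as independent with either sign equally likely, although 6 of 7 were lower in NSG in each donor. Such a common tilt raises agreement by itself, so that the binomial p overstates the evidence. Independent chance outgrowth cannot be told apart from a host effect, since the count depends on the pseudocount and the values do not tell whether a barcode in both donors is 1 clone.

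Splitting the 8 disease samples 4 against 4 in all 35 ways, the strains and the tissues each gave 0 limma calls without a block, a count that all 35 splits reach by construction, so that these splits say nothing about chance. The highest other count was 1043, from the split by donor, and the other 32 splits, which mix donors, strains and tissues, gave 0. The count of the split by donor points to the separate clone sets of the donors as the main structure of the samples. With donor as a block, limma called 10 clones between strains with 1 mean per group, 0 with marrow and spleen averaged, and 64 with 1 mean per side of a split. Among the 18 splits with 2 samples of each donor on each side, 1, the real one, gave as many as 64, and the highest other gave 31, with the strains exchanged in 1 donor. Only the real split and that one keep marrow and spleen of each donor and strain on the same side. The others part them in at least 1 donor and gave at most 6 calls, which is no fair comparison. This leaves too few splits to separate the strain count from chance.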

How the results depend on the processing

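Settings named here as added were chosen after seeing the data, namely those on the largest clone, all GFP barcodes, uneven libraries, colour shares, counts within donors and the block joined with another setting. By inverse Simpson numbers the strain difference in diversity reversed (log2 -0.074) and that of disease shrank to -0.052 (exact permutation p = 0.68). Without the 2 samples whose libraries differ, the disease differences were -1.56 for diversity, -1.47 for BFP and 0.91 for mCHERRY (exact permutation p = 0.0667 each, the smallest then allowed). Without either donor they ranged from -2.05 to -1.08, -2.11 to -0.92 and 0.86 to 0.93, where the design allows no p below 0.2, and BFP without donor 2 had an exact permutation p of 0.6. Similarity between strains was 0.925 by Morisita-Horn (0.935 between disease and baseline). By Bray-Curtis it was 0.443 without the largest clone and 0.451 without GFP barcodes. The baseline top 50 held 43.4% of disease reads. A top 10 drawn again without the largest clone held 7.73% of the remaining reads, with 31.5% in donor 1 PTPRCA spleen and at most 2.98% in donor 2. Drawn again without GFP barcodes, it held 0.149% of the remaining reads. At 0.1% of reads, 3 clones were dominant in both donors (Fisher's exact p = 0.0333), and at 5%, 1 clone. Without the largest BFP clone of each sample, added later, the BFP share of donor 2 turned from a log2 NSG over PTPRCA of -0.48 to 0.44.

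Clones over 4-fold apart by strain, and by tissue, numbered 542 and 54 in donor 1 and 408 and 27 in donor 2 with a pseudocount of 1, 87 and 2 and 60 and 1 with 100, and 104 and 4 and 65 and 4 with the 1000 CPM filter. At 8-fold they numbered 174 and 0 and 127 and 1, and at 2-fold 564 and 97 and 511 and 71. Strain counts exceeded tissue counts in each of these settings.

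With donor as a replicate block, limma called 10 clones between strains and 5 between disease and baseline. It called 0 between tissues. With the block and the pseudocount of 1 CPM, that of 100 CPM, no filter, the 1000 CPM filter, no largest clone or no GFP barcodes, the counts were 18, 1, 0, 6, 14 and 16 between strains, 6, 28, 0, 5, 4 and 1 between disease and baseline, and 0 throughout between tissues. With the block on the mean of marrow and spleen, they were 0 between strains and 2 between disease and baseline, so that the block calls depend on these choices. Without the block, limma called 0 clones in all 18 settings, which says nothing about stability. That fit recovered 0% of clones changed between strains in simulated data with donors apart, and changes by disease or tissue were not simulated. Of all settings of the results that answer a comparison, 64 kept direction and side of the threshold or moved little, these 18 among them. A further 27 moved by more, 10 fell short of the threshold, 14 newly passed it, and 1 reversed. Movement was set against a spread only for similarity and the baseline list. Most of the 27 were counts of clones, which had no spread. Leaving out samples raises the smallest p that can be reached, and the cause of the other changes was not tested. With 1 mean per group, leaving out a donor leaves limma no residual degrees of freedom, so that fit gave no count. The fit of strain and tissue within each donor, added later, called 0 clones between strains, with 333 and 284 at an unadjusted p under 0.05. It has 1 residual degree of freedom per clone, so that these 0 calls say little. The edgeR alternative was not run because no single step gave whole reads, and no repeat columns existed to use alone. Depth set a floor of 0.289 to 0.580 CPM, below which loss of a clone was not detectable.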

Other observations

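The comparisons in this part were chosen after the data were seen. Barcodes that were listed at 0 in both baselines and reached 10 CPM at disease lay mainly in NSG samples of donor 1. Of 2243 such barcodes with reads, 269 reached 10 CPM in an NSG sample and 11 in a PTPRCA sample of donor 1, and 69 and 77 did in donor 2. The NSG samples of both donors shared 28 of them, against 8.28 for independent lists, and the PTPRCA samples shared 1, against 0.378. None of the 28 reached 10 CPM in a PTPRCA sample. Among the shared barcodes were GFP_Barcode_40977, at 488 CPM in donor 1 NSG spleen and 11609 CPM in donor 2 NSG bone marrow, and mCHERRY_2_Barcode_805948, at 2101 CPM in donor 1 NSG spleen and 75.8 CPM in donor 2 NSG bone marrow. These values carry no test of whether the barcodes were transplanted below the detection limit or passed between NSG samples.

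At 100 CPM or more, barcodes listed at 0 in the donor's own baseline numbered 4 and 18 in NSG bone marrow and spleen of donor 1 and 9 and 5 in those of donor 2. In the PTPRCA samples they numbered 1 and 1 in donor 1 and 0 and 0 in donor 2. In donor 2 NSG bone marrow they held 1.48% of reads, most of it in GFP_Barcode_40977.

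The 2 libraries of donor 1 PTPRCA spleen ranked clones differently. Over 262 clones of 100 to 1000 CPM, since larger values were not split into libraries, the first correlated with donor 1 PTPRCA bone marrow at a Spearman's rho of 0.626 and the second at -0.0347, across clones, which are not independent replicates. In donor 1 NSG bone marrow, both libraries correlated with NSG spleen, at 0.496 and 0.374 over 435 clones.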
